A study of Mus musculus with 9 samples.

How the data were processed

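Gene expression was measured in the round, flat and hypertrophic layers of the growth plate of the proximal tibia of newborn (age 0 days) wild-type Black Swiss mice. Per the labels' protocols, unfixed hind limbs were frozen, each layer was dissected by hand from cryosections under a microscope, and 18 to 20 tibiae of 1 litter made up a sample. RNA was purified on columns with DNase treatment, and 2.7 to 4.6 µg, given as a range over samples, was labelled by a one-cycle protocol and hybridised to Affymetrix mouse genome arrays. The 9 samples are 3 layers from each of 3 litters. The labels record no sex, and the dissection includes no step that isolates chondrocytes from other cells.

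The values are MAS5 signal intensities that were deposited as 1 table of 45101 probe sets by 9 arrays and were made with Affymetrix Expression Console and its MAS5 algorithm, per the submitters' processing notes, with versions not given in the sources used here. In the deposited intensity table each array has the same mean (500.003) after 2% of its values at either end are left out, so the arrays were already scaled to a common level on the linear scale. Detection calls and scanner images were not used here. The median signal of an array lay between 123 and 152, and 0 pairs of arrays were identical.

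Of the probe sets, 64 are controls. Among the other 45037, 34945 were assigned to 1 gene, 932 to several and 9160 to no gene named in the annotation used here, and 34741 were matched by gene identifier. This gave 18193 genes. Signals were transformed as log2(signal + 26), where the pseudocount of 26 is the 20th percentile of all values, so a fold change understates the difference for genes near that level. Each gene was represented by its single-gene probe set with the highest mean, and genes whose mean lay above the median of the non-control probe sets (7.212 on the log2 scale) were tested, 11313 in all. The 3'/5' ratios of the actin and Gapdh control probe sets described RNA integrity.

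Differences between layers were tested with limma 3.58.1 in R 4.3.3 with a term for each layer and a fixed block for litter. Variances were moderated with a mean-variance trend (residual degrees of freedom 4, prior degrees of freedom 8.15), and p was adjusted by the Benjamini-Hochberg method within each contrast with a threshold of 0.05. Every adjusted p of a gene in the text is from limma, and every adjusted p of a list is from camera in the same package. The median standard error of a log2 difference was 0.179. In the text, flat minus round, hypertrophic minus flat and hypertrophic minus round are the contrasts, and rose, fell and changed are used only for genes past the threshold. Genes that differed in any layer came from limma's F test. A gene counted as highest or lowest in a layer when both of its contrasts passed in that direction. Because these contrasts share arrays, the counts were set beside 20 data sets simulated with no effect.

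The litter block rests on the labels, whose replicate number marks a litter. It was also checked in the data: the deviations of 2 arrays of the same litter from their layer means correlated across genes with r of 0.167 to 0.517 in all 9 pairs, against -0.434 to 0.081 in the 18 pairs of different litters. The duplicate correlation estimated by limma was 0.257. All of these pairs join arrays of different layers. The deviations of each layer sum to 0, so a deviation shared within litters also lowers the correlations between litters. The ranges are therefore not independent of each other.

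Gene lists were written from general knowledge before the data were examined, as were the model, the thresholds, the rule for named genes and the first set of alternatives. The 32 lists are resting and periarticular chondrocyte markers, flat columnar chondrocyte markers, prehypertrophic chondrocyte markers, hypertrophic chondrocyte markers, cartilage matrix genes, bone and mineralised matrix genes, mineralisation and phosphate handling, matrix proteases and inhibitors, S phase and DNA replication, G2 and mitosis, CDK inhibitors and cell cycle exit, hedgehog pathway, PTHrP and cAMP pathway, Wnt ligands, targets and antagonists, BMP and TGF-beta pathway, FGF pathway, IGF and growth hormone pathway, hypoxia response and glycolysis, oxidative phosphorylation, cholesterol biosynthesis, ER stress and secretory pathway, chondrocyte transcription factors, primary cilium and cytoskeletal polarity, perichondrium, fibroblast and tendon markers, osteoblast markers, osteoclast markers, erythroid markers, macrophage markers, neutrophil and myeloid precursor markers, endothelial markers, skeletal muscle markers, and sex-linked transcripts. They hold 592 genes, 555 of them among the genes named on the array. Lists with at least 5 tested members (31, the sex-linked transcripts excepted) were tested with camera with a preset correlation between genes of 0.01, and the median log2 difference of the tested members is given. Camera with a correlation estimated from the residuals, and fry, were alternatives. Counts of risen and fallen members use the adjustment over all tested genes, and those adjusted over the list alone are given beside them. A list's score on an array is the mean log2 value of its tested members minus its mean over the 9 arrays.

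Named genes were, in each contrast, the 8 largest rises and the 8 largest falls among genes past the threshold that moved the same way in all 3 litters, up to 4 members of each list with the largest change among those past the threshold (or the 2 of highest mean signal where no member passed), and 12 genes chosen to check the labels: Pthlh, Sfrp5, Ucma, Prg4, Fgfr3, Col2a1, Ihh, Pth1r, Col10a1, Mmp13, Ibsp and Mki67. Of these 12, 10 were tested. Pthlh was not among the genes named here, and Ihh lay below the filter. Names that are not official symbols were passed over among the largest changes. The remaining probe sets of named genes were inspected in 133 of 334 combinations of gene and contrast that had any, and 0 had a probe set past the threshold in the opposite direction. Fold changes are given without a sign, and signals as mean ± SD of 3 arrays.

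The testing steps were run on simulated data in which known genes were changed among 11313. Between flat and round, limma recovered 31.3% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes (67, 67 and 66 genes), with 7.6% of calls false. Between hypertrophic and flat it recovered 34.3%, 89.6% and 97.0%, with 6.4% of calls false. When the oxidative phosphorylation genes were shifted by a log2 value of 0.5 between flat and round, camera called that list and 0 others. Camera called the list with an estimated correlation too (adjusted p = 0.00517). The simulated noise was independent between genes, whereas the correlation that camera estimated for this list in the data was 0.611. The simulation therefore does not show how the list tests behave with correlated genes.

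The alternatives fixed in advance were no litter block, litter as a random block, only the 2 layers compared, pseudocounts of 6.5 and 104, quantile normalization, centring on array medians, no filter, a filter at the 75th percentile, every probe set tested, the mean of all probe sets of a gene, no variance trend, a robust variance prior, the list tests above, and leaving out each litter and each array in turn. Chosen after the data were seen were cyclic loess normalization, leaving out the round array of litter 1 together with the flat array of litter 3, and the skeletal muscle score as a covariate beside the litter block. That score is the mean of the muscle markers, so the covariate removes their own difference by construction. Other splits of the arrays into groups of 3 were refitted. Probe sets with several genes or without a named gene were left out of the main tests. Tables were handled with pandas 2.3.3 in Python 3.11.15 and drawn with matplotlib 3.10.9.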

Results

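The series measured messenger RNA in 3 layers of the growth plate of the proximal tibia of newborn mice (age 0 days). In this cartilage small round chondrocytes near the joint give way to flat chondrocytes stacked in columns, which then enlarge as hypertrophic cells before bone replaces them. The round, flat and hypertrophic layers were dissected by hand from frozen sections, with no sort or marker of cell identity in the protocol. Each layer was hybridised to 3 arrays, 1 for each of 3 litters, so that the 9 arrays formed 3 matched sets and every comparison below has n = 3 litters. Each sample pooled 18 to 20 tibiae of 1 litter of 9 to 10 wild-type pups. Median signals lay between 123 and 152 on the 9 arrays, and the number of arrays limits the precision. Across genes, which are not independent replicates, Pearson's r between arrays of a layer was 0.946 to 0.974 in the round, 0.941 to 0.958 in the flat and 0.96 to 0.97 in the hypertrophic layer.

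The first principal component held 42.5% of the variance and separated the layers, with the round arrays at -43.51 to -34.32, the flat arrays at 3.23 to 10.51 and the hypertrophic arrays at 30.05 to 33.43. The second (20.3%) set the flat array of litter 3 apart, at 44.17. That array also had the highest skeletal muscle score, the mean log2 value of 18 muscle markers relative to all arrays, at 1.34. The other flat arrays scored 0.41 and 0.44, the round arrays -0.33, -0.93 and -0.23, and the hypertrophic arrays -0.91, -0.32 and 0.54 in litters 1 to 3. The score is relative, and muscle signal was high in every layer. Among all tested genes the median muscle marker stood at percentile 96.3, 99.1 and 97.5 in the round, flat and hypertrophic layers. Perichondrium, fibroblast and tendon markers stood at 97.2, 97.2 and 96.7. Signals of different probe sets do not rank genes by abundance. Control probe sets for RNA integrity singled out the round array of litter 1, with a 3'/5' signal ratio of 4.25 for actin and 2.59 for Gapdh, against 1.45 to 2.06 and 0.922 to 1.28 on the other 8 arrays. Sex-linked transcripts were present in all litters, with Xist, expressed from the inactive X chromosome, at mean log2 values of 13.54, 13.02 and 12.95 and the Y-linked Eif2s3y at 8.66, 8.86 and 8.91 in litters 1 to 3. Kdm5d and Uty, also Y-linked, lay between 7.83 and 8.18 and between 7.11 and 8.06.

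Genes chosen in advance to check the layer labels had clear gradients for the most part. Prg4, which encodes the joint lubricant lubricin, had a mean signal of 15342 ± 3014 (SD, n = 3) in the round layer, 385 ± 281 in the flat and 199 ± 54.4 in the hypertrophic layer. Ucma, made by upper-zone chondrocytes, stepped down from 1985 ± 160 to 594 ± 7.50 and 109 ± 27.0. Col10a1, the collagen X gene of hypertrophic cells, had signals of 139 ± 111, 664 ± 239 and 11857 ± 918, and Mmp13, a collagenase of late hypertrophic cells, had 4805 ± 1290, 9881 ± 2097 and 34828 ± 2145. Pth1r, the receptor for parathyroid hormone-related protein, was at 1578 ± 228, 7971 ± 3075 and 12248 ± 1250, and Ibsp, bone sialoprotein, at 3989 ± 1570, 23710 ± 7811 and 43630 ± 4330. The cartilage collagen gene Col2a1 was at 32059 ± 6936, 21585 ± 6323 and 18514 ± 2425. Sfrp5, a Wnt antagonist of resting cells, and the proliferation marker Mki67 passed the threshold in no contrast, with adjusted p of 0.975, 0.385 and 0.265 for Sfrp5 and 0.391, 0.478 and 0.0688 for Mki67 (flat against round, hypertrophic against flat, hypertrophic against round). Fgfr3, a receptor that restrains chondrocyte proliferation, passed only between the hypertrophic and round layers (log2 0.86 ± 0.16, SE), with adjusted p of 0.0699 and 0.14 in the other contrasts. Ihh lay below the expression filter, with mean signals of 79.6 ± 65.6, 81.0 ± 61.9 and 184.5 ± 70.0, and Pthlh is not among the genes named here.

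**Figure D1:**
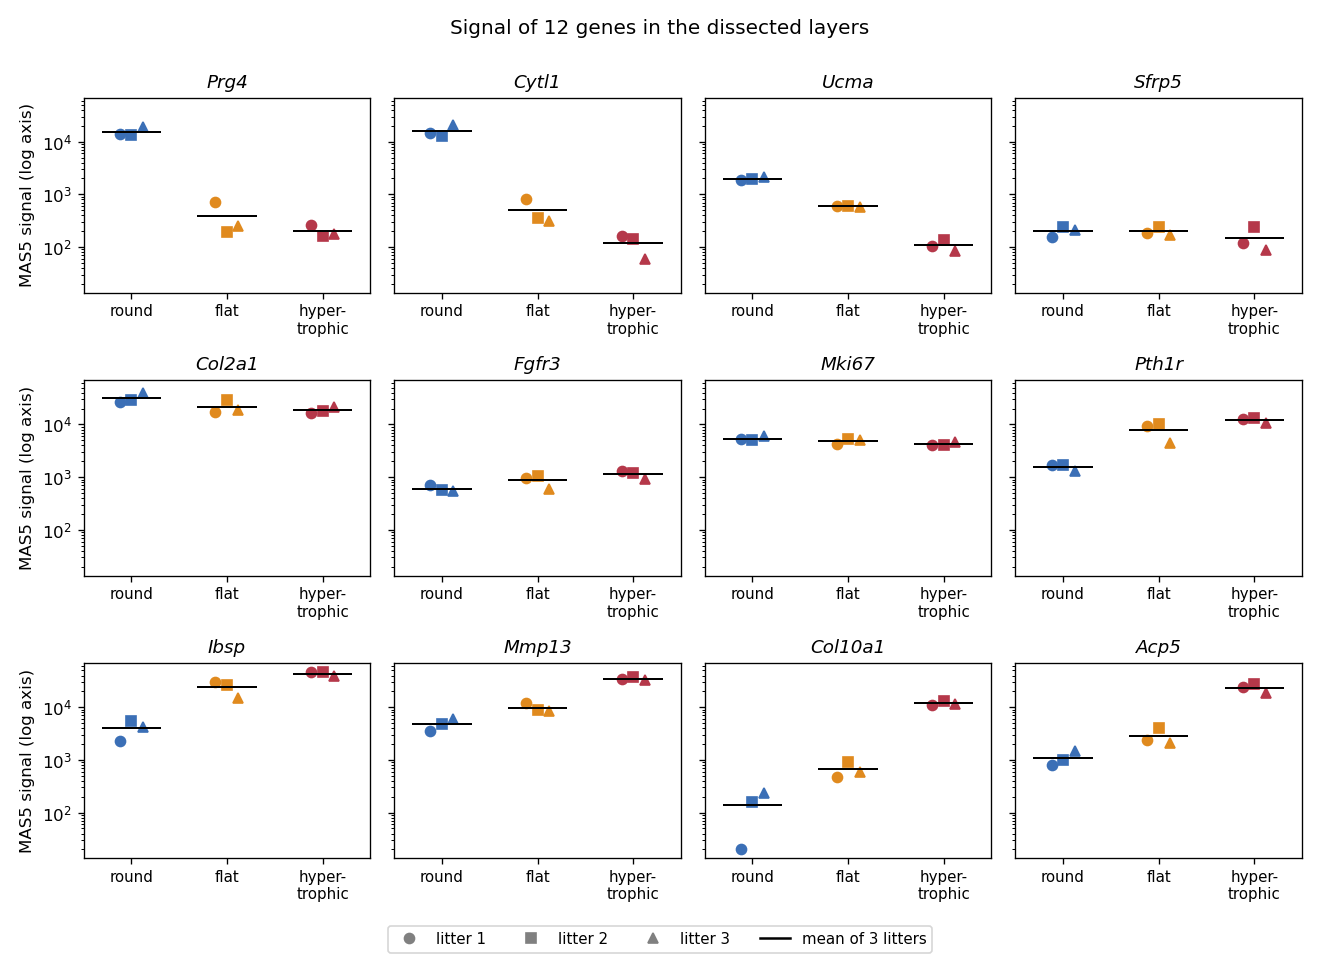
MAS5 signal (log axis) of 12 genes in the round, flat and hypertrophic layers. Each marker is 1 array, its shape gives the litter, and the line is the mean of 3 litters. Prg4, Cytl1 and Ucma have their highest signals in the round layer, Col10a1, Mmp13, Ibsp and Acp5 in the hypertrophic layer, and Sfrp5 and Mki67 passed the threshold in no contrast.

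The first comparison sets the dissected flat layer against the round layer. Prg4 was 42.7-fold lower in the flat layer (log2 -5.42 ± 0.27, SE, n = 3 litters), Cytl1, a secreted cytokine-like protein of cartilage, 32.9-fold lower (-5.04 ± 0.29), and Barx1, a homeobox gene of joint-forming tissue, was lower as well (-4.25 ± 0.30). In the other direction Stra6, a retinol receptor, was 16.8-fold higher (4.07 ± 0.31), and Panx3, a channel protein of prehypertrophic cells and osteoblasts, 12.8-fold higher (3.68 ± 0.25). Ifitm5, a membrane protein of bone-forming cells, rose by 3.55 ± 0.24 and Alpl, the phosphatase that starts mineralisation, by 3.52 ± 0.16. Further among the 8 largest rises were Smpd3, a sphingomyelinase needed for mineralisation (3.12 ± 0.20), Pdzrn4 (3.11 ± 0.53), the Wnt inhibitor Apcdd1 (2.95 ± 0.25) and the chloride channel protein Clic6 (3.15 ± 0.31). Clic6 was not past the threshold with a pseudocount of 6.5 in place of 26. The remaining largest falls were Anxa8 (-4.20 ± 0.29), Adgrg2 (-3.35 ± 0.16), the BMP antagonist Smoc1 (-3.19 ± 0.18), Ngef (-3.08 ± 0.40) and Htra4 (-3.05 ± 0.38). Adjusted p for these 16 genes lay between 4.42e-07 and 0.00155.

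Among the 15 tested resting and periarticular chondrocyte markers, 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median log2 difference of -1.70. Besides Prg4, Cytl1 and Barx1 they included the transcription factor Osr2 (-1.96 ± 0.35) and Ucma (-1.70 ± 0.18). The list passed the camera test with adjusted p = 1.88e-09, and adjusted p = 0.319 with an estimated correlation. Of 13 flat columnar markers, 7 fell and 1 rose (8 and 2 adjusted over the list alone; median -0.49, adjusted p = 0.00715, and adjusted p = 0.458 with an estimated correlation). Among all tested genes the median member stood at percentile 85.2, 64.9 and 64.9 in the round, flat and hypertrophic layers. The list therefore did not single out the flat layer and gives its label no support. Hapln1, which links aggrecan to hyaluronan (-2.39 ± 0.15), and Sox5 (-1.76 ± 0.20), a partner of Sox9, were lower in the flat than in the round layer, and the calmodulin-binding peptide Pcp4 was higher (2.14 ± 0.25). The list's camera call was lost with the round array of litter 1 and the flat array of litter 3 left out together, a choice made after the data were seen. The cartilage matrix list shares Col2a1, Acan, Matn3, Comp and Hapln1 with the flat columnar list, so the lists are not independent. Of 23 cartilage matrix genes, 10 were lower and 1 higher (10 and 2 adjusted over the list alone; median -0.26, adjusted p = 0.00238, and adjusted p = 0.423 with an estimated correlation). Examples were Prelp (-1.92 ± 0.17) and Cilp (-1.90 ± 0.15), both matrix proteins. Col2a1 fell by 0.59 ± 0.17 (adjusted p = 0.0306). The difference of Col2a1, flat minus round, had adjusted p of 0.114 without the litter block and of 0.0542, 0.137, 0.16, 0.164 and 0.0541 without the round 1, flat 1, round 3, flat 3 and hypertrophic 3 arrays.

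Prehypertrophic, hypertrophic and bone genes were higher in the flat layer. These lists share members and are not independent. Ibsp and Dmp1 stand in the hypertrophic, bone and osteoblast lists, and Mef2c and Bmp6 in the prehypertrophic and hypertrophic lists. Of 10 prehypertrophic markers, 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Sp7 (2.58 ± 0.23) and Runx3 (2.56 ± 0.25), transcription factors of the bone lineage, and Pth1r (2.24 ± 0.17). The median was 1.04, with adjusted p = 5.52e-07, and adjusted p = 0.319 with an estimated correlation. Hypertrophic markers rose in 7 and fell in 2 of 13 (7 and 3 adjusted over the list alone; median 1.05, adjusted p = 0.00238), with Dlx5 at 2.81 ± 0.28, Ibsp at 2.59 ± 0.26 and Col10a1 at 2.35 ± 0.36. Bone and mineralised matrix genes rose in 5 of 9 (5 adjusted over the list alone; median 0.94, adjusted p = 0.000125), including osteomodulin, Omd (1.97 ± 0.16), and the phosphoprotein gene Dmp1 (1.97 ± 0.22). Osteoblast markers, 6 of which stand in another list too, rose in 7 of 10 (7 adjusted over the list alone; median 1.42, adjusted p = 1.18e-06). These last 3 lists each had adjusted p = 0.319 with an estimated correlation. Mineralisation and phosphate handling genes split, with 4 higher and 5 lower of 12 (4 and 5 adjusted over the list alone): the citrate transporter Slc13a5 rose by 2.54 ± 0.25 and the mineralisation inhibitor Mgp fell by 1.44 ± 0.17. Their median (-0.14) and mean (0.51) differ in sign, and adjusted p was 0.606. Matrix proteases and inhibitors changed in 3 up and 3 down of 20 (3 and 4 adjusted over the list alone; median -0.15, adjusted p = 0.348). Mmp9, a gelatinase, was at 1.77 ± 0.14, Mmp13 at 1.05 ± 0.20 and the serine protease Htra1 at -1.66 ± 0.13.

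Marker lists of other cell types moved alongside these gene groups. Skeletal muscle markers rose in 16 of 18 (17 adjusted over the list alone; median 1.19, adjusted p = 2.38e-13), with Neb, nebulin of the thin filament, at 1.92 ± 0.19 and Ttn, titin, at 1.69 ± 0.20. Osteoclast markers rose in 8 and fell in 1 of 14 (8 and 1 adjusted over the list alone; median 0.91, adjusted p = 0.0018), with Acp5, the tartrate-resistant phosphatase, at 1.36 ± 0.23 and Ctsk, cathepsin K, at 1.30 ± 0.15. Neutrophil and myeloid precursor markers rose in 4 of 5 (5 adjusted over the list alone; median 1.39, adjusted p = 0.000106), with S100a8 at 1.44 ± 0.18. Each of these 3 lists had adjusted p = 0.319 with an estimated correlation. Macrophage markers rose in 3 of 17 (3 adjusted over the list alone; median 0.26, adjusted p = 0.0128, and adjusted p = 0.365 with an estimated correlation), a call lost in 6 further alternatives, the fits without the round or the flat array of litter 1 and fry (adjusted p = 0.067) among them. Erythroid markers rose in 2 of 5 (2 adjusted over the list alone; median 0.25, adjusted p = 0.115). Endothelial markers fell in 5 and rose in 1 of 16 (6 and 1 adjusted over the list alone; median -0.32, adjusted p = 0.00755, and adjusted p = 0.365 with an estimated correlation). The transcription factor Erg, which is also a resting and periarticular marker, fell by 1.91 ± 0.18. Perichondrium, fibroblast and tendon markers went both ways, with 2 higher and 3 lower of 18 (2 and 3 adjusted over the list alone; median -0.01, adjusted p = 0.57). Dermatopontin, Dpt, and the collagen gene Col14a1 were the clearest, at -2.55 ± 0.28 and -1.18 ± 0.14.

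**Figure D2:**
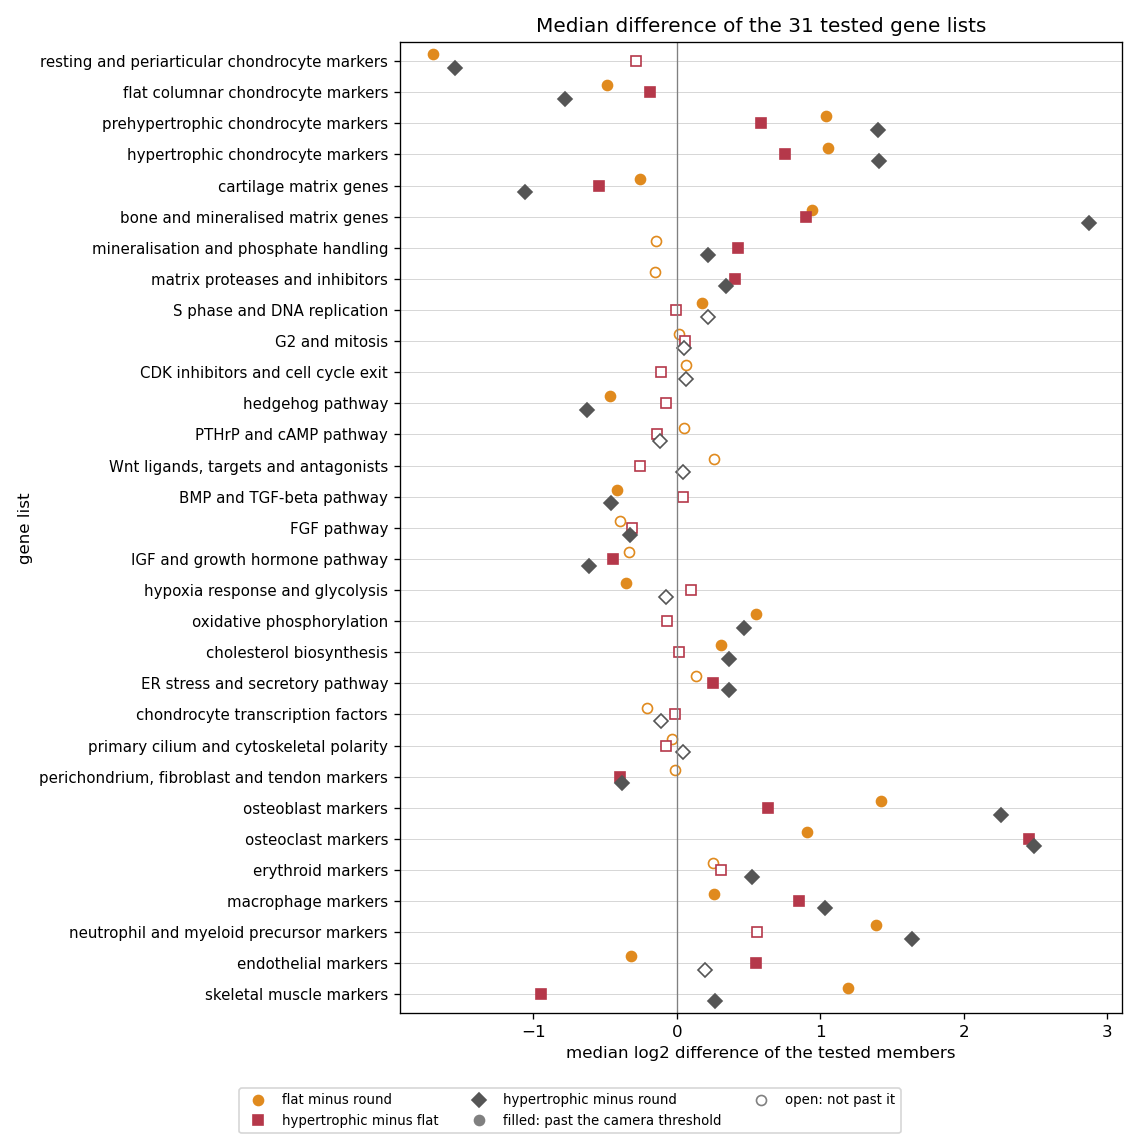
Median log2 difference of the tested members of 31 gene lists in the 3 contrasts (x axis, 0 marks no difference). Circles stand for flat minus round, squares for hypertrophic minus flat and diamonds for hypertrophic minus round, and a filled marker passed camera with the preset correlation (18, 15 and 22 lists). With an estimated correlation camera passed 0 lists in each contrast (3, 2 and 3 at an unadjusted p under 0.05), and fry passed 21, 12 and 24.

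Oxidative phosphorylation genes rose in 15 of 25 and fell in 0 (21 and 0 adjusted over the list alone; median 0.55, adjusted p = 1.88e-09, and adjusted p = 0.319 with an estimated correlation). Ndufa4, a respiratory chain subunit, rose by 0.92 ± 0.13 and Uqcrfs1, of complex III, by 0.76 ± 0.15. The skeletal muscle score rose with them, and with it as a covariate 1 of the 25 was past the threshold as higher. Hypoxia response and glycolysis genes fell in 7 and rose in 2 of 29 (9 and 2 adjusted over the list alone; median -0.36, adjusted p = 0.00201, and adjusted p = 0.319 with an estimated correlation), and with that covariate 2 remained lower. Carbonic anhydrase 9, Car9, fell by 2.05 ± 0.19 and Ndrg1, a hypoxia-induced gene, fell by 0.95 ± 0.13. The round array of litter 1, with the high 3'/5' ratios, enters both lists: without it 20 oxidative phosphorylation genes rose and 9 hypoxia and glycolysis genes fell. Cholesterol biosynthesis genes rose in 3 and fell in 1 of 20 (3 and 1 adjusted over the list alone; median 0.31, adjusted p = 0.0128, and adjusted p = 0.319 with an estimated correlation). The farnesyl diphosphate synthase Fdps was at 1.06 ± 0.17. Endoplasmic reticulum stress and secretory genes rose in 5 and fell in 3 of 26 (5 and 3 adjusted over the list alone; median 0.14, adjusted p = 0.28), with the glutathione-degrading enzyme Chac1 at 1.03 ± 0.22.

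In the hedgehog pathway 6 of 15 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.47, adjusted p = 0.00148, and adjusted p = 0.325 with an estimated correlation). The co-receptors Cdon and Boc were at -2.65 ± 0.25 and -1.90 ± 0.16. In the BMP and TGF-beta pathway 13 of 34 fell and 3 rose (15 and 5 adjusted over the list alone; median -0.42, adjusted p = 0.00152, and adjusted p = 0.347 with an estimated correlation). The growth factors Bmp2 and Gdf5 were at -1.96 ± 0.16 and -1.70 ± 0.25. The FGF pathway fell in 6 and rose in 2 of 15 (9 and 4 adjusted over the list alone; median -0.40, adjusted p = 0.111), with Fgf7 at 1.19 ± 0.20. IGF and growth hormone genes fell in 6 and rose in 1 of 16 (7 and 1 adjusted over the list alone; median -0.34, adjusted p = 0.0767), with the insulin receptor substrate Irs1 at 0.88 ± 0.13. Wnt genes rose in 4 and fell in 6 of 31 (9 and 7 adjusted over the list alone; median 0.26, adjusted p = 0.398), with the ligand Wnt5a at 1.33 ± 0.19 and the antagonist Wif1 at -1.86 ± 0.23. PTHrP and cAMP genes rose in 2 and fell in 1 of 14 (2 and 1 adjusted over the list alone; adjusted p = 0.398), with a median of 0.05 that turned to -0.01 when arrays were centred on their medians. Chondrocyte transcription factors rose in 5 and fell in 11 of 27 (6 and 13 adjusted over the list alone; median -0.21, adjusted p = 0.101). Primary cilium and polarity genes rose in 5 and fell in 2 of 17 (5 and 2 adjusted over the list alone), with a median of -0.03 against a mean of 0.04 and adjusted p = 0.656. The intraflagellar transport gene Ift80 fell by 1.10 ± 0.19.

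Few cell cycle genes passed the threshold between the flat and round layers. Of 31 genes of G2 and mitosis, 0 passed the limma test (0 adjusted over the list alone, 3 at an unadjusted p under 0.05; median 0.02, which became -0.04 with median centring; adjusted p = 0.803). Mki67 was at -0.16 ± 0.12 and Cdc20, an activator of the anaphase-promoting complex, at -0.18 ± 0.11. S phase genes rose in 1 of 28 (0 adjusted over the list alone, 4 at an unadjusted p under 0.05; median 0.18), and camera gave adjusted p = 0.0482, and adjusted p = 0.319 with an estimated correlation. That list lost its call in 14 alternatives besides the estimated correlation, among them the fits without the litter block and without round 1, flat 1, round 2 or flat 2. CDK inhibitors and cell cycle exit genes rose in 3 of 13 (3 adjusted over the list alone; median 0.06, adjusted p = 0.0904): Gadd45g, a stress-induced regulator (1.65 ± 0.18), Cdkn1a, the CDK inhibitor p21 (0.90 ± 0.12), and Rb1 (0.97 ± 0.19).

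By limma with litter as a block, 1926 of 11313 genes (17.0%) differed between the flat and round layers, 949 higher and 977 lower, of which 945 and 971 moved the same way in all 3 litters. A change of at least 2-fold was found in 425 higher and 307 lower genes, and with arrays centred on their medians the share higher was 39.7% in place of 49.3%. The count was 935 without the litter block, 1225 without the round array of litter 2, 1034 without litter 2, 1129 without litter 3 and 526 with the muscle score as covariate, a fit chosen after the data were seen. Of the 109 named genes past the threshold, 57 were not past it with that covariate, among them Osr2, Ucma, Sox5, Mgp, Gdf5, Wif1, Cdkn1a, Fgf7, Ift80, Htra4 and Ndufa4. Without the litter block 31 were not, among them Uqcrfs1 and Chac1. With the covariate the cartilage matrix list was not past camera's threshold, with a median of -0.24 and a members' median SE of 0.35 in place of 0.17. The muscle list was not past it either, which was fixed in advance, since its members make up the score. The hedgehog, BMP and TGF-beta, hypoxia, cholesterol and endothelial lists were also not past the threshold with the covariate. Among lists past the threshold, medians moved by it more than 1.5 times were -0.97 for resting and periarticular markers, -0.16 for hedgehog, -0.20 for BMP and TGF-beta, -0.18 for hypoxia, 0.22 for oxidative phosphorylation, 0.19 for cholesterol, -0.19 for endothelial, 0.08 for muscle, 0.50 for macrophage, 0.34 for S phase and 2.30 for osteoblast genes. The hypoxia list also lost its call without litter 2, the flat columnar and endothelial lists without litter 3, and the cholesterol list with the stricter filter. Among lists past the threshold, leaving out 1 array moved the median more than 1.5 times for cartilage matrix (-0.51 without flat 2, -0.02 without flat 3), S phase (0.09 without round 1), BMP and TGF-beta (-0.26 without round 2), hypoxia (-0.23 without round 2, -0.19 without flat 2) and macrophage genes (0.12 without round 1 or flat 1). Among the others the sign changed with 1 array left out for G2 and mitosis (-0.02 to 0.11), CDK inhibitors and exit (-0.08 to 0.22), cilium (-0.07 to 0.13) and perichondrium genes (-0.08 to 0.07), and with the covariate for proteases (0.07), cilium (0.21) and perichondrium genes (0.02). Further medians of lists not past the threshold moved more than 1.5 times with 1 array left out, with ranges of 0.04 to 0.45 for Wnt, -0.43 to -0.19 for IGF, 0.01 to 0.10 for PTHrP, -0.18 to -0.08 for mineralisation, -0.22 to -0.07 for protease, 0.07 to 0.16 for secretory and -0.33 to -0.18 for transcription factor genes.

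The second comparison sets the dissected hypertrophic layer against the flat layer. Col10a1 rose 17.9-fold (log2 4.16 ± 0.36, SE, n = 3 litters), Dmp1, an acidic phosphoprotein of mineralising matrix, 7.01-fold (2.81 ± 0.22) and Mmp13 3.56-fold (1.83 ± 0.20). Genes of bone-resorbing osteoclasts stood beside them: Acp5 rose 8.31-fold (3.05 ± 0.23), Atp6v0d2, a proton pump subunit, 6.81-fold (2.77 ± 0.25), and Ocstamp (3.29 ± 0.38) and Dcstamp (2.86 ± 0.37), which mediate osteoclast fusion, 9.76-fold and 7.27-fold. The other large rises were granzyme E, Gzme (2.89 ± 0.32), and the matricellular gene Ccn5 (2.77 ± 0.37). Vwf, the platelet-binding factor of vessel walls, fell most (-2.63 ± 0.25), with Cpxm2 (-2.55 ± 0.20), Ucma (-2.22 ± 0.18), Ccn3 (-2.13 ± 0.16) and Itgbl1 (-1.98 ± 0.17) among the 8 largest falls. The rest of these were Cidea, a lipid droplet protein (-2.54 ± 0.46), Myh11, smooth muscle myosin (-2.05 ± 0.42), and Dcx, a microtubule-associated protein (-2.05 ± 0.43), the last not past the threshold without the flat 1, hypertrophic 1 or hypertrophic 2 array. Adjusted p for these 16 genes lay between 1.66e-05 and 0.00883.

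Osteoclast markers rose in 13 of 14 (13 adjusted over the list alone; median 2.45, adjusted p = 2.36e-20, and adjusted p = 0.153 with an estimated correlation). Macrophage markers rose in 9 and fell in 1 of 17 (9 and 2 adjusted over the list alone; median 0.85, adjusted p = 0.000346), with the signalling adaptor Tyrobp at 1.47 ± 0.15 and the receptor Csf1r at 1.07 ± 0.13. Endothelial markers rose in 9 and fell in 1 of 16 (11 and 1 adjusted over the list alone; median 0.55, adjusted p = 1.7e-05), led by VE-cadherin, Cdh5 (1.15 ± 0.14), whereas Vwf alone of them fell. Skeletal muscle markers fell in 14 of 18 (17 adjusted over the list alone; median -0.95, adjusted p = 1.88e-12), with Ttn at -1.22 ± 0.20 and Neb at -1.20 ± 0.19. Perichondrium, fibroblast and tendon markers fell in 7 and rose in 1 of 18 (9 and 2 adjusted over the list alone; median -0.40, adjusted p = 0.00038), with Col14a1 at -1.62 ± 0.14 and tenomodulin, Tnmd, at -1.59 ± 0.19. These 4 lists each had adjusted p = 0.303 with an estimated correlation. Neutrophil and myeloid precursor markers rose in 2 of 5 (3 adjusted over the list alone; median 0.56, adjusted p = 0.0586). Erythroid markers rose in 0 of 5 by limma (0 adjusted over the list alone, 3 at an unadjusted p under 0.05; median 0.31, adjusted p = 0.118).

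**Figure D3:**
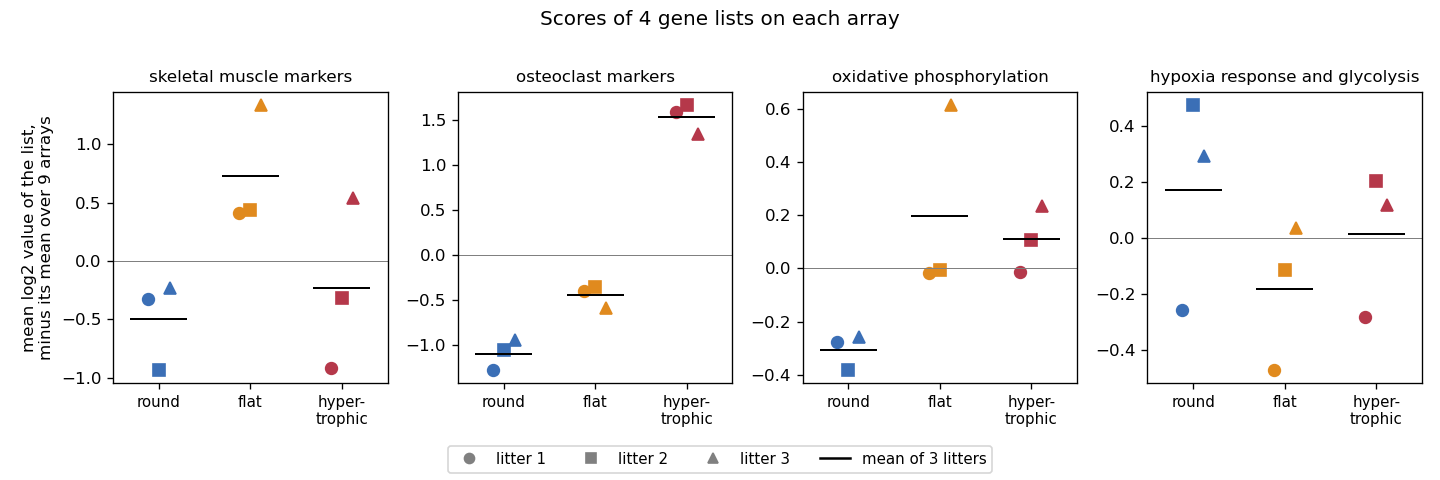
Scores of 4 gene lists on each array (y axis, mean log2 value of the tested members minus its mean over the 9 arrays). Each marker is 1 array, its shape gives the litter, and the line is the mean of 3 litters. Within each litter muscle markers are highest on the flat array (0.41, 0.44 and 1.34) and osteoclast markers on the hypertrophic arrays (1.60, 1.67 and 1.35).

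Matrix and mineral genes changed together with these marker lists, and several of the lists share members. Hypertrophic markers rose in 7 of 13 and fell in 0 (7 and 1 adjusted over the list alone; median 0.75, adjusted p = 2.66e-05). With the muscle score as covariate 3 of them rose and the median was 0.07. Bone and mineralised matrix genes rose in 5 of 9 (5 adjusted over the list alone; median 0.90, adjusted p = 0.000343), with Phex, a regulator of phosphate handling, at 2.55 ± 0.19 and Ifitm5 at 1.29 ± 0.24. Mineralisation genes rose in 5 of 12 (5 adjusted over the list alone; median 0.43, adjusted p = 8.79e-05), with the pyrophosphate transporter Ank at 1.41 ± 0.16 and Slc13a5 at 1.65 ± 0.25. Matrix proteases and inhibitors rose in 7 of 20 and fell in 0 (11 and 1 adjusted over the list alone; median 0.40, adjusted p = 2.66e-05), with Mmp9 at 2.62 ± 0.14, an osteoclast marker too, and the inhibitor Timp1 at 1.36 ± 0.17. Cartilage matrix genes fell in 11 and rose in 1 of 23 (14 and 2 adjusted over the list alone; median -0.55, adjusted p = 2.66e-06). Among them were Matn4, a matrilin (-1.95 ± 0.23), and the small leucine-rich proteoglycans Epyc (-1.51 ± 0.25), Prelp (-1.36 ± 0.17) and Fmod (-1.56 ± 0.19). These 5 lists each had adjusted p = 0.303 with an estimated correlation. Prehypertrophic markers rose in 4 of 10 (7 adjusted over the list alone; median 0.58, adjusted p = 0.00135). Osteoblast markers rose in 4 of 10 (6 rose and 1 fell adjusted over the list alone; median 0.63, adjusted p = 0.00191). Both lists had adjusted p = 0.376 with an estimated correlation, and fry gave adjusted p = 0.112 and 0.119. With the muscle covariate neither passed camera, their medians were 0.23 and 0.12, and 0 prehypertrophic markers (4 without it) and 1 osteoblast marker rose by limma. Flat columnar markers fell in 3 of 13 (6 fell and 2 rose adjusted over the list alone; median -0.19, adjusted p = 0.0353, and adjusted p = 0.585 with an estimated correlation). Sox5 was at -1.93 ± 0.20, and the list's call was lost in 6 further alternatives, fry (adjusted p = 0.171), the muscle covariate and the fits without the flat or the hypertrophic array of litter 2 among them. Resting and periarticular markers fell in 3 and rose in 2 of 15 (3 and 3 adjusted over the list alone; median -0.29, adjusted p = 0.147), with Cytl1 at -1.79 ± 0.29 and the Wnt antagonist Wif1 at 1.35 ± 0.23.

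Among the signalling and metabolic lists, IGF and growth hormone genes fell in 5 of 16 and rose in 0 (9 and 0 adjusted over the list alone; median -0.45, adjusted p = 7.24e-06, and adjusted p = 0.303 with an estimated correlation). Among them were Igf1 (-1.08 ± 0.14), the binding protein gene Igfbp5 (-0.85 ± 0.16) and the growth hormone receptor Ghr (-0.67 ± 0.13). The muscle, osteoclast and macrophage lists shifted in the same contrast, as given above. Endoplasmic reticulum stress and secretory genes rose in 6 of 26 (9 adjusted over the list alone; median 0.25, adjusted p = 0.000682, and adjusted p = 0.303 with an estimated correlation). Hypoxia and glycolysis genes rose in 7 and fell in 1 of 29 (7 and 1 adjusted over the list alone; median 0.10, adjusted p = 0.0661), with the stress-induced mTOR inhibitor Ddit4 at 1.32 ± 0.21. Wnt genes rose in 5 and fell in 7 of 31 (6 and 12 adjusted over the list alone; median -0.26, adjusted p = 0.212), with the antagonists Dkk1 at 2.20 ± 0.32 and Sfrp2 at -1.68 ± 0.15. BMP and TGF-beta genes rose in 6 and fell in 8 of 34 (7 and 8 adjusted over the list alone; median 0.04, adjusted p = 0.936), with Bmp2 at 1.36 ± 0.16 and Bmp8a at 1.71 ± 0.32. Hedgehog genes rose in 1 and fell in 3 of 15 (3 and 5 adjusted over the list alone; median -0.07, adjusted p = 0.459). FGF genes rose in 1 and fell in 4 of 15 (2 and 5 adjusted over the list alone; median -0.31, adjusted p = 0.233). PTHrP and cAMP genes rose in 1 and fell in 2 of 14 (1 and 2 adjusted over the list alone; median -0.14, adjusted p = 0.103). The transcription factor Zfp521 of the last list fell by 0.88 ± 0.15. Chondrocyte transcription factors rose in 3 and fell in 7 of 27 (4 and 9 adjusted over the list alone; adjusted p = 0.762), with a median of -0.01 that became 0.06 with median centring. Cilium and polarity genes rose in 1 and fell in 3 of 17 (1 and 4 adjusted over the list alone; median -0.08, adjusted p = 0.257), Prickle1 at -1.06 ± 0.15.

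Cell cycle and housekeeping metabolism showed few calls between these layers. S phase genes fell in 1 of 28 (1 adjusted over the list alone; adjusted p = 0.967), with a median of -0.003, against an upward direction in camera, that became 0.07 with median centring. G2 and mitosis genes passed in 0 of 31 by limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05; median 0.06, adjusted p = 0.74), with Mki67 at -0.16 ± 0.12. Among CDK inhibitors and exit genes 1 rose and 1 fell of 13 (1 and 1 adjusted over the list alone; median -0.11, adjusted p = 0.631), the faller being Cdkn1c, the CDK inhibitor p57 (-0.74 ± 0.14). Oxidative phosphorylation genes passed in 0 of 25 by limma (0 adjusted over the list alone, 3 at an unadjusted p under 0.05; adjusted p = 0.268), with a median of -0.07 that became 0.003 with median centring, and Cox4i1 at 0.09 ± 0.12. Cholesterol biosynthesis genes passed in 0 of 20 by limma (0 adjusted over the list alone, 4 at an unadjusted p under 0.05; median 0.02, adjusted p = 0.947), with Hmgcs1 at 0.04 ± 0.13. Pth1r rose by 0.70 ± 0.17 (adjusted p = 0.0171) and Ibsp by 0.94 ± 0.26 (adjusted p = 0.0356). The difference of Pth1r, hypertrophic minus flat, had adjusted p of 0.176 without the litter block and of 0.0555, 0.0654 and 0.134 without the hypertrophic 1, flat 3 and hypertrophic 3 arrays. That of Ibsp, hypertrophic minus flat, had 0.111 without the block and 0.167, 0.127, 0.0685, 0.176 and 0.141 without hypertrophic 1, flat 2, hypertrophic 2, flat 3 and hypertrophic 3.

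By limma 1283 genes (11.3%) differed between the hypertrophic and flat layers, 692 higher and 591 lower, and each moved the same way in all 3 litters. Changes of at least 2-fold were found in 245 higher and 236 lower genes, and with median centring the share higher was 65.2% in place of 53.9%. The count was 553 without the litter block, 239 with the muscle score as covariate, 698, 591, 692 and 732 without the flat 1, hypertrophic 1, hypertrophic 2 and hypertrophic 3 arrays, and 709, 604 and 724 without litters 1, 2 and 3. With the covariate 63 of the 96 named genes past the threshold were lost, among them Ocstamp, Dcstamp, Gzme, Cidea, Wif1, Fmod, Ifitm5, Slc13a5, Igf1, Ghr, Dkk1 and Tnmd, whereas Col10a1, Acp5, Dmp1, Mmp13, Mmp9, Phex, Sox5, Bmp2 and Cdh5 kept their calls in every alternative run. Without the litter block 36 were lost, among them Myh11, Dcx, Ttn, Neb and Ddit4, and 0 of the 18 muscle markers fell. The muscle list was not past camera's threshold with the covariate, which was fixed in advance, since its members make up the score. The secretory and endothelial lists were also not past the threshold with the covariate. Besides the lists given with it above, it moved the medians of bone matrix (0.44), macrophage (0.49), endothelial (0.33) and muscle genes (-0.13) more than 1.5 times among lists past the threshold, and 6 osteoclast markers in place of 13 rose with it (median 2.07). Fry gave adjusted p = 0.0513 for cartilage matrix genes and 0.0612 for muscle markers. Among lists past the threshold, leaving out 1 array moved the median more than 1.5 times for flat columnar (-0.04 without flat 2, -0.40 without flat 3), mineralisation (0.23 without flat 3), osteoblast (0.34 without flat 3), macrophage (0.55 without hypertrophic 2) and muscle genes (-0.61 without hypertrophic 1). Among the others the sign changed with 1 array left out for S phase (-0.04 to 0.07), G2 and mitosis (-0.03 to 0.09), hedgehog (-0.18 to 0.06), BMP and TGF-beta (-0.06 to 0.09), oxidative phosphorylation (-0.16 to 0.11), cholesterol (-0.05 to 0.07), transcription factor (-0.05 to 0.16) and cilium genes (-0.18 to 0.02). With the covariate it changed for G2 and mitosis (-0.19), BMP and TGF-beta (-0.21), oxidative phosphorylation (0.11) and cholesterol genes (-0.02). Further medians of lists not past the threshold moved more than 1.5 times with 1 array left out, with ranges of -0.44 to -0.12 for FGF, -0.42 to -0.19 for resting, -0.20 to -0.02 for CDK inhibitor and exit and 0.02 to 0.20 for hypoxia genes.

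The third comparison spans the growth plate from the round to the hypertrophic layer. Col10a1 was 90.7-fold higher in the hypertrophic layer (log2 6.50 ± 0.36, SE, n = 3 litters), Ocstamp 31.1-fold (4.96 ± 0.38), Panx3 29.2-fold (4.87 ± 0.25), Ifitm5 28.8-fold (4.85 ± 0.24) and Dmp1 27.5-fold (4.78 ± 0.22). The remaining largest rises were Acp5 (4.42 ± 0.23), Mmp9 (4.39 ± 0.14) and Smpd3 (4.31 ± 0.20). Cytl1 was 113.5-fold lower (-6.83 ± 0.29), Prg4 68.8-fold (-6.11 ± 0.27) and Barx1 20.7-fold (-4.37 ± 0.30). The other large falls were Cpxm2 (-4.24 ± 0.20), Cdon (-4.15 ± 0.25), Adgrg2 (-3.96 ± 0.16), Ucma (-3.91 ± 0.18) and Dpt (-3.83 ± 0.28). Adjusted p for these 16 genes lay between 5.08e-09 and 1.47e-06, and all of them kept their calls in every alternative run.

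Chondrocyte marker lists, several of which share members, separated the ends of the growth plate. Resting and periarticular markers fell in 9 and rose in 1 of 15 (9 and 1 adjusted over the list alone; median -1.55, adjusted p = 1.48e-07). Cartilage matrix genes fell in 16 and rose in 2 of 23 (16 and 2 adjusted over the list alone; median -1.06, adjusted p = 7.95e-08). Matn4, Prelp and Fmod were at -3.49 ± 0.23, -3.28 ± 0.17 and -2.69 ± 0.19. Prehypertrophic markers rose in 8 of 10 (8 adjusted over the list alone; median 1.41, adjusted p = 9.88e-08). Hypertrophic markers rose in 8 of 13, with 2 lower (8 and 2 adjusted over the list alone; median 1.41, adjusted p = 3.01e-05). Bone matrix genes rose in 5 of 9 (5 adjusted over the list alone; median 2.87, adjusted p = 3.01e-05). Osteoblast markers rose in 7 of 10 (7 rose and 1 fell adjusted over the list alone; median 2.26, adjusted p = 4.8e-06). All 6 lists had adjusted p = 0.226 with an estimated correlation. Flat columnar markers fell in 8 and rose in 3 of 13 (8 and 3 adjusted over the list alone; median -0.78, adjusted p = 0.00209, and adjusted p = 0.405 with an estimated correlation). Sox5 was at -3.69 ± 0.20, Acan, the aggrecan gene, at -1.21 ± 0.16 and Col2a1 at -0.78 ± 0.17, whereas Fgfr3 was higher. Mineralisation genes rose in 5 and fell in 3 of 12 (5 and 3 adjusted over the list alone; median 0.22, adjusted p = 0.0485, and adjusted p = 0.432 with an estimated correlation), with Alpl at 4.27 ± 0.16. Proteases and inhibitors rose in 7 and fell in 3 of 20 (10 and 4 adjusted over the list alone; median 0.35, adjusted p = 0.036, and adjusted p = 0.402 with an estimated correlation). The first call was lost in 10 further alternatives and the second in 6. Both were lost without the round array of litter 1, the first also without round 2 or flat 2 and the second also without hypertrophic 1.

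Osteoclast markers rose in 13 of 14 (13 adjusted over the list alone; median 2.49, adjusted p = 8.53e-14). Macrophage markers rose in 9 of 17, with 1 lower (10 and 1 adjusted over the list alone; median 1.03, adjusted p = 9.47e-05), Cd68 at 2.36 ± 0.20. Neutrophil and myeloid precursor markers rose in 5 of 5 (5 adjusted over the list alone; median 1.64, adjusted p = 5.99e-05), with S100a8 at 2.13 ± 0.18. Erythroid markers rose in 3 of 5 (3 adjusted over the list alone; median 0.52, adjusted p = 0.0152), a call lost without a variance trend or with a robust prior. These 4 lists had adjusted p = 0.226 with an estimated correlation. Perichondrium, fibroblast and tendon markers fell in 8 and rose in 3 of 18 (9 and 3 adjusted over the list alone; median -0.39, adjusted p = 0.0126, and adjusted p = 0.315 with an estimated correlation), with Col14a1 at -2.80 ± 0.14. Endothelial markers rose in 3 and fell in 2 of 16 (3 and 2 adjusted over the list alone; median 0.20, adjusted p = 0.193). Skeletal muscle markers rose in 2 of 18 (1 adjusted over the list alone; median 0.27, adjusted p = 0.0465, and adjusted p = 0.618 with an estimated correlation). That call was lost in 16 further alternatives, among them fry (adjusted p = 0.434) and the muscle covariate (median 0.05). Because the covariate is the mean of these same markers, that loss was fixed in advance. The call was also lost in the fits without the litter block and without any 1 of round 2, flat 2, hypertrophic 2, round 3 and hypertrophic 3. In contrast, 10 muscle markers rose without the round array of litter 1 and 15 without both that array and the flat array of litter 3. The median was 0.63 without round 1, 0.58 without hypertrophic 1, 0.09 without round 2, 0.14 without hypertrophic 2, 0.15 without round 3 and 0.10 without hypertrophic 3.

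Oxidative phosphorylation genes rose in 13 of 25 (17 adjusted over the list alone; median 0.47, adjusted p = 4.8e-06, and adjusted p = 0.386 with an estimated correlation), with Ndufa4 at 1.08 ± 0.13. Here 11 rose with the muscle score as covariate and 20 without the round array of litter 1. Endoplasmic reticulum stress and secretory genes rose in 12 and fell in 1 of 26 (14 and 4 adjusted over the list alone; median 0.36, adjusted p = 0.00196, and adjusted p = 0.248 with an estimated correlation). Chac1 was at 1.92 ± 0.22, the secretory transcription factor Creb3l1 at 1.18 ± 0.15 and the protein disulfide isomerase Pdia4 at 1.04 ± 0.23. Cholesterol genes rose in 4 and fell in 1 of 20 (5 and 1 adjusted over the list alone; median 0.37, adjusted p = 0.0277, and adjusted p = 0.226 with an estimated correlation), a call lost in 6 further alternatives, among them the fit without the round array of litter 2. Hypoxia and glycolysis genes rose in 3 and fell in 6 of 29 (3 and 6 adjusted over the list alone; median -0.07, adjusted p = 0.253), with Car9 at -2.75 ± 0.19 and Ddit4 at 1.58 ± 0.21. S phase genes rose in 4 and fell in 1 of 28 by limma (0 adjusted over the list alone, 9 at an unadjusted p under 0.05; median 0.22, adjusted p = 0.0914). G2 and mitosis genes rose in 3 and fell in 1 of 31 (0 adjusted over the list alone, 7 at an unadjusted p under 0.05; median 0.05, adjusted p = 0.682). CDK inhibitors and exit genes rose in 3 and fell in 1 of 13 (3 and 1 adjusted over the list alone; median 0.06, adjusted p = 0.542), with Gadd45g at 2.13 ± 0.18 and Cdkn1a at 1.37 ± 0.12.

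Among the signalling lists, IGF and growth hormone genes fell in 9 and rose in 1 of 16 (12 and 1 adjusted over the list alone; median -0.61, adjusted p = 9.56e-06, and adjusted p = 0.226 with an estimated correlation). Igfbp5 and Igf1 were at -1.44 ± 0.16 and -1.25 ± 0.14. Hedgehog genes fell in 8 and rose in 1 of 15 (8 and 1 adjusted over the list alone; median -0.63, adjusted p = 0.00775). BMP and TGF-beta genes fell in 16 and rose in 5 of 34 (17 and 6 adjusted over the list alone; median -0.46, adjusted p = 0.00343). Both lists had adjusted p = 0.386 with an estimated correlation. Cdon and Boc (-2.70 ± 0.16) fell while Ptch1, the hedgehog receptor and target, rose by 1.56 ± 0.22. Gdf10 fell by 2.64 ± 0.21 while Bmp8a rose by 3.14 ± 0.32. FGF genes fell in 5 and rose in 1 of 15 (5 and 1 adjusted over the list alone; median -0.33, adjusted p = 0.0285, and adjusted p = 0.226 with an estimated correlation), with the ligand Fgf18 at -2.21 ± 0.21. That list lost its call in 5 further alternatives, among them the fits without the litter block and without the round array of litter 2, and its median was -0.22 with the muscle covariate. Wnt genes rose in 8 and fell in 10 of 31 (8 and 11 adjusted over the list alone), with a median of 0.04 against a mean of -0.008 and adjusted p = 0.78, Sfrp2 at -2.85 ± 0.15 and Dkk1 at 2.83 ± 0.32. PTHrP and cAMP genes rose in 1 and fell in 4 of 14 (1 and 5 adjusted over the list alone), with a median of -0.12 against a mean of 0.02 and adjusted p = 0.542, the kinase-regulated repressor Hdac4 at -0.75 ± 0.17. Chondrocyte transcription factors rose in 8 and fell in 12 of 27 (9 and 12 adjusted over the list alone; median -0.11, adjusted p = 0.245), with Sp7 at 3.33 ± 0.23. Cilium and polarity genes rose in 3 and fell in 4 of 17 (4 and 6 adjusted over the list alone), with a median of 0.04 against a mean of -0.08 and adjusted p = 0.818, and Ift80 at -1.30 ± 0.19.

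By limma 2840 genes (25.1%) differed between the hypertrophic and round layers, 1405 higher and 1435 lower, with 463 and 549 of at least 2-fold. The count was 1824 without the litter block, 1770 without the hypertrophic array of litter 2, 1568 without litter 2, and 4601 when every probe set was tested by itself. Of the 111 named genes past the threshold, 80 kept their calls in every alternative run. With 1 array left out, the medians of the mineralisation list (0.14 without round 3) and the FGF list (-0.16 without round 2) moved more than 1.5 times. Those of lists not past the threshold did so for S phase (0.09 to 0.26, the lowest without round 1), G2 and mitosis (0.01 to 0.14), hypoxia (-0.18 to -0.03), transcription factor (-0.20 to -0.06), cilium (0.01 to 0.15) and endothelial genes (0.14 to 0.30). The sign changed for CDK inhibitors and exit genes (-0.11 to 0.13), PTHrP and cAMP genes (-0.21 to 0.05) and Wnt genes (-0.20 to 0.14), with the lowest value without round 1 for the first and last of these.

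A test for any difference among the layers called 3208 genes (28.4%), 1789 without the litter block and 4956 over every probe set, and 1822 and 2043 without litters 2 and 3. A gene was counted as highest or lowest in a layer when both of its contrasts were past the threshold in that direction. The round layer was highest for 685 genes, such as Prg4, Cytl1, Barx1 and Acan, and lowest for 543. The hypertrophic layer was highest for 474, such as Col10a1, Mmp13 and Acp5, and lowest for 314. The flat layer was highest for 215 and lowest for 122. Vwf was among the 215, with the muscle genes Casq1, calsequestrin, and Ttn. Chosen after their values were seen, other members are the cartilage matrilin Matn1 (0.80 ± 0.19 against round and -1.15 ± 0.19 from flat to hypertrophic) and the secreted hedgehog-binding protein Scube2 (1.44 ± 0.17 and -1.38 ± 0.17). Because the contrasts share arrays, data simulated with no effect were scored too, and gave a mean of 0, 0.05 and 0 genes highest in the round, hypertrophic and flat layers (at most 1 in 20 simulations). Few genes pass any contrast when no layer differs, so these counts do not show what shared arrays add when layers differ. Independent lists of these sizes would overlap by 123.9, 85.9 and 49.6 genes. Part of the excess over that overlap may come from the shared arrays, since 3 arrays cannot be split into parts of 2. For the flat layer the splits of the arrays, given below, do not exclude chance. Without the litter block the counts of highest genes were 403, 261 and 29, and with the muscle score as covariate 229, 88 and 25, in the round, hypertrophic and flat layers. Genes highest in the round layer numbered 452 without round 2, and 373 and 438 without litters 2 and 3. Genes highest in the hypertrophic layer numbered 298, 242, 253 and 261 without flat 1, hypertrophic 1, hypertrophic 2 and hypertrophic 3, and 262, 213 and 249 without litters 1, 2 and 3. Genes highest in the flat layer numbered 119, 70, 101 and 126 without flat 1, hypertrophic 1, flat 3 and hypertrophic 3, 136, 116 and 103 without litters 1, 2 and 3, 102 with litter as a random block and 140 without a variance trend.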

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

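The tests of muscle RNA and of RNA quality were chosen only after the results were seen. Signal was found in data that the comparisons above leave out. When every probe set was tested, 2894 of 22518 had no gene named here, and of these limma called 271 between flat and round (123 higher, 148 lower), 148 between hypertrophic and flat (73 higher, 75 lower) and 514 between hypertrophic and round (216 higher, 298 lower). What they measure was not tested. The control probe sets singled out 1 sample: the round array of litter 1 had a 3'/5' ratio of 4.25 for actin and 2.59 for Gapdh, with the other 8 arrays at 1.45 to 2.06 and 0.922 to 1.28.

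Of 25 oxidative phosphorylation genes, 15 were higher and 0 lower in the flat than in the round layer, with a median of 0.55. The list had adjusted p = 1.88e-09 by camera, and 0.319 with an estimated correlation. Without the round array of litter 1 the median was 0.67 (bootstrap SE over members 0.045) and 20 of 25 genes rose. The difference therefore did not depend on that array. Bootstrap SEs here and below treat members as independent and do not measure the spread between litters. In litters 1 to 3 the list scored -0.28, -0.38 and -0.26 on the round arrays and -0.02, -0.01 and 0.615 on the flat arrays. The flat array of litter 3, with the highest muscle score, thus carries much of the rise. With 1 array left out the median was 0.39 to 0.67. With the muscle score as covariate the median was 0.22 (SE 0.08), 1 gene in place of 15 was called, and the members' median SE went from 0.14 to 0.30, so the calls ended through smaller differences and wider errors alike. Muscle RNA may be a source of part of this difference, and because the score differs between the layers it cannot be told apart from a difference between the chondrocytes, which stays open and untested. Between hypertrophic and round, where the muscle scores lie closer, the median was 0.47, and 0.38 with the covariate, with 13 and 11 genes called as higher.

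Of 29 hypoxia response and glycolysis genes, 7 were lower and 2 higher in the flat than in the round layer, with a median of -0.36. The list had adjusted p = 0.00201 by camera, and 0.319 with an estimated correlation. The median was -0.49 (bootstrap SE 0.113) without the round array of litter 1, with 9 of 29 genes lower. The difference therefore did not depend on that array. With 1 array left out the median was -0.49 to -0.19. With the muscle score as covariate the median was -0.18 (SE 0.09), with 2 in place of 7 genes lower and a members' median SE of 0.35 in place of 0.17. Whether muscle RNA lowers these genes in the flat layer cannot be told apart from a difference between the layers' chondrocytes, because the 3 flat arrays have the highest muscle scores of their litters. A difference in oxygen supply between the layers stays open and was not tested.

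Osteoclast markers were higher in the hypertrophic than in the flat layer, with 13 of 14 called and a median of 2.45. Mean signals in the round, flat and hypertrophic layers were 2279, 7840 and 48386 for Mmp9, 1090.3, 2870.0 and 23336 for Acp5 and 1575, 3997 and 7444 for Ctsk, and 2 of the 14 stand in another list. Signals of different probe sets do not rank genes by abundance. Muscle RNA diluting the flat layer would raise the other genes in step, but the cartilage matrix median was -0.55 (bootstrap SE 0.25). A change of cartilage matrix genes between these layers would also lower that median, so it cannot decide the question. Over all 11313 tested genes the median log2 difference, hypertrophic minus flat, was -0.005, with 692 genes higher and 591 lower by limma. Without a common rise of the other genes, these values argue against dilution alone as the source of the osteoclast median of 2.45. With the muscle score as covariate the osteoclast median was 2.07, so most of the difference stayed, though 6 in place of 13 genes were called. The members' median SE was then 0.33 in place of 0.20. Cells of the osteoclast lineage in the hypertrophic pieces and expression by hypertrophic chondrocytes both stay open, since either would raise the osteoclast markers and no test here separates them. Macrophage markers rose in 9 and fell in 1 of 17 in the same contrast, with a median of 0.85.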

How the results depend on the processing

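The tests with the muscle score as covariate, without both arrays in doubt and with cyclic loess were chosen only after the results were seen. Over the alternatives, named genes gave 7993 values with an unchanged call, 923 that were no longer past the threshold, 6 newly past it and 8 with the opposite sign, and lists gave 2391 unchanged, 147 lost and 60 gained. Without the replicate block of litter, limma called 935 (flat against round), 553 (hypertrophic against flat) and 1824 genes (hypertrophic against round), all among the calls with it, 1789 in any layer, and 403, 29 and 261 highest in the round, flat and hypertrophic layers. That fit also ended the calls of the S phase list (flat against round) and of the FGF and muscle lists (hypertrophic against round). The spread between litters then enters the error, and how far this alone ended the calls was not tested. A random replicate block left 102 genes highest in the flat layer, and no variance trend 140, and the cause was not tested. Testing every probe set gave 4601 (hypertrophic against round) and 4956 (any layer), since more was tested. Camera with an estimated correlation passed 0, 0 and 0 lists (3, 2 and 3 at an unadjusted p under 0.05, and 21, 12 and 24 by fry). A higher correlation is not the whole cause. The S phase and cholesterol lists, flat minus round, had estimated correlations of 0.005 and -0.005, below the preset 0.01. Their camera adjusted p went from 0.0482 and 0.0128 to 0.319. For the FGF list, hypertrophic minus round (correlation -0.024), it went from 0.0285 to 0.226. The rest of the cause was not tested. With the muscle score as covariate 526 (flat against round, 396 shared) and 239 genes (hypertrophic against flat, 190 shared) were called, and 229, 25 and 88 were highest in the round, flat and hypertrophic layers. The median SE of all genes went from 0.18 to 0.37 and 0.31 in those contrasts, which is part of the cause. With that covariate the sign was opposite for Ccne1, flat minus round (-0.49), Fgfr4, flat minus round (-0.042), Myh3, flat minus round (-0.29), Edem1, hypertrophic minus flat (-0.14), S100a9, hypertrophic minus flat (-0.023), and Myh8, hypertrophic minus flat (0.072). With the mean of all probe sets it was opposite for Kif23, hypertrophic minus round (0.058), and Msmo1, hypertrophic minus round (-0.053), and the cause was not tested. Leaving out each litter or array in turn gave 1034 to 1956, 591 to 1658 and 1568 to 2924 genes in the 3 contrasts, 1822 to 3312 in any layer, 373 to 683, 70 to 289 and 213 to 540 highest in the round, flat and hypertrophic layers, and 17 to 19, 14 to 18 and 18 to 22 lists. The highest of these gene counts came without the round array of litter 1, or without flat 3 for hypertrophic against round, and the cause was not tested. Of the named genes past the threshold, 45 of 109, 28 of 96 and 80 of 111 kept their calls in every alternative run in the 3 contrasts. The number of arrays, 3 for each layer, limits precision, and without detection calls the signal over background was not assessed.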

Other observations

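The genes in the next paragraph were chosen only after their values were seen, and no alternatives were run for them in the contrasts given, whereas the splits of the arrays were planned.

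Several further genes differed between neighbouring layers. Sox9, the transcription factor that specifies cartilage, fell by 1.57 ± 0.20 from round to flat (SE, n = 3 litters, limma adjusted p = 0.000198). Trps1, a GATA-type repressor in chondrocytes, had its fall between round and flat (-1.50 ± 0.15), with a difference of -0.01 ± 0.15 from flat to hypertrophic. The BMP-responsive genes Id1 and Id4 fell by the flat layer too (-1.08 ± 0.13 and -0.99 ± 0.17), with 0.02 ± 0.13 and 0.11 ± 0.17 in the next step. Creb5, a transcription factor of articular progenitors, was at -2.39 ± 0.21 between flat and round, and Pappa2, a protease that frees IGF from its binding proteins, at -2.37 ± 0.23. Mef2c, which drives hypertrophy in cartilage and also acts in muscle, rose by 1.06 ± 0.11 in the flat layer and was at -0.06 ± 0.11 between flat and hypertrophic. In the hypertrophic layer Cemip, a hyaluronan-degrading protein, rose by 2.75 ± 0.18 over flat, Hpgd, which inactivates prostaglandins, by 2.20 ± 0.19, and Itgb3, an integrin abundant in osteoclasts, by 2.58 ± 0.15. The osteoclast and muscle lists moved in these contrasts, as given in the report.

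Other splits of the arrays were refitted to see how large a result they give. For 2 layers with 3 arrays each there are 10 splits, too few for a share under 0.05. In each contrast 1 of the 10, the real one, gave as many genes (1926, 1283 and 2840, against at most 0 in the others by limma, which had at most 841, 676 and 600 at an unadjusted p under 0.05). Likewise 1 of the 10 splits gave as many lists (18, 15 and 22, against at most 13, 13 and 14). Of 280 splits of the 9 arrays into 3 groups, a litter block can be fitted to 252, and 100 of these were drawn. Of the 100, 17 exchange arrays only within litters, as the litter block requires. There are 36 such splits in all, and each was refitted. As many genes differing in any layer came from 1 of the 100, the real one (3208 against at most 678). Within litters it was 1 of the 36, with at most 567 in the others, so chance is unlikely for that count. For the genes highest in the round layer (685) and in the hypertrophic layer (474) it was 1 of the 100 and 1 of the 36 each. The others had at most 339, and chance is unlikely for these counts too. For the genes highest in the flat layer (215) it was 5 of the 100, so these splits do not exclude chance. The other 4 kept the 3 round arrays together, so their counts hold the real difference of the round layer. The 20 data sets simulated with no effect had at most 0 genes highest in the flat layer by limma. No layer differs in those data sets, so they cannot decide this question. Among the 36 splits within litters, 4 gave as many as the 215 of the flat layer.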
